A study of Mus musculus with 36 samples.

How the data were processed

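Total RNA from the spleen and liver of male BALB/c mice was measured on 36 Illumina BeadChip arrays after biotin labelling, 18 arrays per tissue in 6 groups of 3. Per the labels, every mouse had been inoculated under the skin with J558 cells, a mouse myeloma line, and drank either distilled water or oil palm phenolics (OPP, a polyphenol extract) at 1500 ppm gallic acid equivalents. The time field gives 18 hours, 1 week or 4 weeks, with ages of 6, 7 and 10 weeks, and was read as the time after inoculation. The treatment text of every sample, however, says 4 weeks after inoculation, and the labels do not make clear when the drinks began, so the meaning of the times is not settled. The labels do not state whether a replicate is 1 mouse or a pool. The p-values therefore rest on the spread between arrays within groups, pooled over the 6 groups of a tissue.

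The deposited value table of the authors gives, for 23982 probes, a linear ratio of each probe to its own median over the 18 arrays of the same tissue. This was checked on the file: the median of every row was within 0.0011 of 1 in both tissues. The ratios keep no absolute level, so a probe near background cannot be told from an abundant one, and the authors' background correction and scaling between arrays are not stated. The lowest ratio is 0.01, reached by 20 spleen values, all in the water group at 1 week, replicate 2. A second deposited table of unnormalised signals and detection p-values was not used, because the names of its 72 columns match no sample label. The planned fit on background-corrected signals was therefore replaced by its stated fallback, the value table. The number of arrays limits the precision.

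Ratios were taken to log2 and fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes), separately in each tissue with a mean per group, leaving 12 residual degrees of freedom. No offset, filter or further scaling was applied. In each tissue OPP was compared with water at each time and averaged over the times, water groups at 1 and 4 weeks were compared with the water group at 18 hours, and a moderated F test asked whether the OPP effect differed between times. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over all probes of a comparison. Gene symbols came from the reference annotation: 19344 probes had 1 symbol, for 14739 genes, and 4638 had none. Differences are OPP minus water, or later minus earlier, on the log2 scale, with the standard error (SE) of the model and 3 arrays per group.

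The groups, comparisons, tests, 34 gene lists and the rule for named genes were chosen before the data were examined. That rule took up to 8 rises and 8 falls (5 and 5 for the comparisons of times) by size among called genes whose groups did not overlap; chance alone separates 3 against 3 arrays in 10% of genes. For averages it asked for the same sign at all 3 times. Where no gene passed it took the 5 with the smallest p, and it added the 4 members with the smallest p of each list that passed, the 6 smallest p of each F test, and Alb and Cd79b, planned as label checks. Because the ratios keep no level, the values of Alb and Cd79b cannot show the tissue of an array. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They were tested again with an estimated correlation and with fry. Each gene stood with its probe of highest SD, because the planned choice by highest mean needs levels. Member counts use that probe alone, so a member can be called on another probe, and are adjusted over all probes and also over the list alone.

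Alternatives planned beforehand and run were a fit to the compared arrays only, the replicate number as a block, array weights, and leaving out each array. Others were chosen after the data were seen: centring each array on its median, quantile normalisation of the log ratios, a robust variance prior, the more variable probes only, and the mean of a gene's probes. The pipeline was tested on simulated data with inserted changes. Every comparison within a tissue was also repeated over other splits of its arrays.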

Results

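The 36 arrays comprised 12 groups of 3: spleen and liver, OPP or distilled water, at 18 hours, 1 week and 4 weeks after inoculation with J558 myeloma cells. Array medians of the log2 ratios lay between -0.06 and 0.00 on the 12 spleen arrays of 18 hours and 1 week, between 0.08 and 0.11 on the spleen arrays of 4 weeks, and between -0.03 and 0.04 in liver. Probes called in the OPP comparisons numbered 0, 2 and 80 in spleen at 18 hours, 1 week and 4 weeks, and 0, 222 and 15 in liver.

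**Figure D1:**
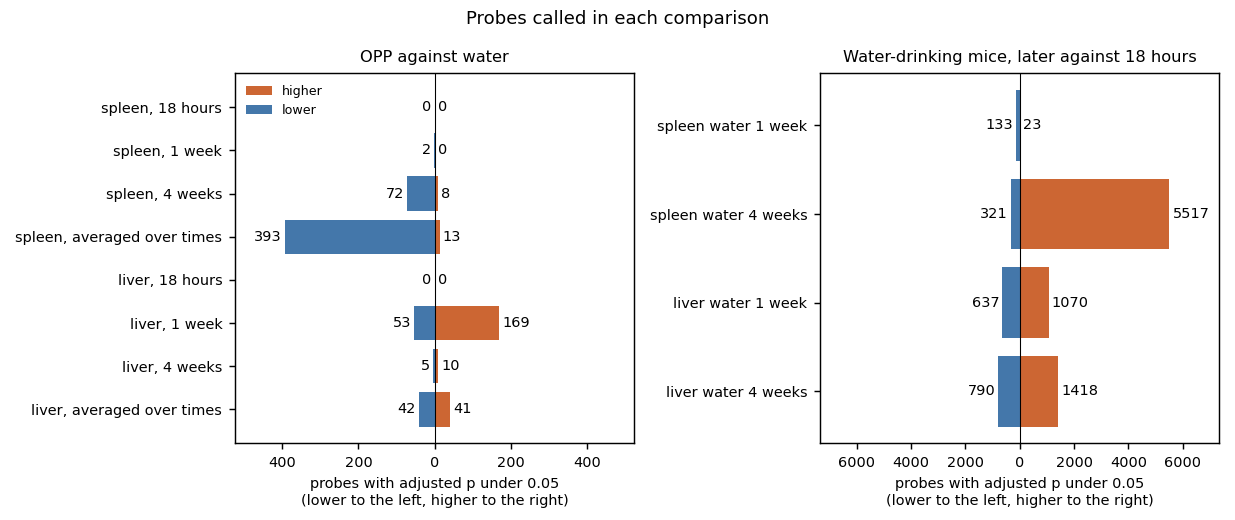
Number of probes called higher (right) and lower (left) in each comparison, OPP against water on the left panel and water-drinking mice at later times against 18 hours on the right panel, on different scales. Liver at 1 week has 169 higher and 53 lower probes with OPP, and spleen at 4 weeks 8 higher and 72 lower.

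The comparison of OPP with water in spleen at 18 hours is at the earliest time sampled. The genes with the smallest p were Olfr69, an olfactory receptor, with a difference of 0.52 (SE 0.10), Dnaic1 with -0.49 (SE 0.10) and Olfr437 with 0.47 (SE 0.10). Hpx, the haem-binding plasma protein haemopexin, had -2.11 (SE 0.45) and Igfbp7 -0.44 (SE 0.10). None passed, each having an adjusted p of 0.426. A second probe of Dnaic1 gave 0.21, and other probes of Igfbp7 gave 0.37 and -0.04. Alb and Cd79b, markers of hepatocytes and B cells, had differences of -0.17 and -0.10. In limma 0 probes were called, with 2615 at an unadjusted p under 0.05, and 0 also with array weights, the replicate number as a block, a robust prior, centring or quantile normalisation. Of the 34 lists, 5 fell in camera, and all 5 had an adjusted p = 0.659 with an estimated correlation. No member of any of them passed over all probes. Acute phase genes (23 measured, 13 lower adjusted over the list alone, camera adjusted p 1.1e-07) had a median of -0.67, with Saa1 at -2.81 and Fga at -2.35. Hepatocyte genes (17 measured, 11 lower adjusted over the list alone, camera adjusted p 1.57e-07) had a median of -0.69, with Apoh at -1.55 and Ambp at -1.43. The hepatocyte median per array was 1.15 and 0.72 in replicates 2 and 3 of the water group, -0.11 in replicate 1, and between -0.14 and -0.07 in the OPP group. Oxidative phosphorylation (54 measured, 2 lower adjusted over the list alone, camera adjusted p 3.27e-09) had a median of -0.23, ribosomal proteins (66 measured, 1 lower adjusted over the list alone, camera adjusted p 1.95e-06) -0.15, and heat shock genes (15 measured, 0 adjusted over the list alone, camera adjusted p 0.00182) -0.24. Among their members, Cox7c stood at -0.36, Rpl23 at -0.42 and Hspa4 at -0.44. Without water replicate 1 the count became 35.

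In spleen at 1 week, Dbp and Ufl1 were the called genes, and both fell with OPP. Dbp, a transcription factor driven by the circadian clock, fell by 1.78 on the log2 scale (SE 0.20, adjusted p 0.000727). Ufl1, an enzyme that attaches the small protein UFM1, fell by 4.26 (SE 0.57, adjusted p 0.00495) on 1 probe, while its other probe gave 0.20. The first probe was high in some arrays and low in others, with no value between 0.46 and 3.25. The circadian clock list (17 measured, camera adjusted p 0.000216) had 1 member that fell and 16 that did not pass. Adjusted over the list alone, 1 was higher and 7 lower. Its adjusted p = 0.624 with an estimated correlation. Beside Dbp, Tef had a difference of -0.86 (SE 0.15), Nr1d2 of -0.67 (SE 0.13) and Nr1d1 of -0.58 (SE 0.11), and none of these 3 passed. Leaving out each array in turn gave 1 to 3 probes, with 1 without water replicate 1, OPP replicate 1 or OPP replicate 3. In these 3 fits Dbp kept its call and Ufl1 did not. With a robust prior Ufl1 also lost its call (adjusted p 0.106), and 1 other probe was called beside Dbp.

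Another 9 lists passed in spleen at 1 week, none with a member called over all probes. Lower were MHC class II (10 measured, camera adjusted p 0.0178, 4 lower adjusted over the list alone), T cells (14, 0.00949, 4 lower adjusted over the list alone), NK and cytotoxic cells (16, 0.0306, 0 adjusted over the list alone), immediate early genes (17, 0.034, 2 lower adjusted over the list alone) and ribosomal proteins (66, 0.000216, 1 lower adjusted over the list alone). Examples were H2-Aa at -0.41, Cd3d at -0.43, Il2rb at -0.40, Rgs1 at -0.97 and Rpl22 at -0.49. Higher were cell cycle (27, 0.000241), erythroid cells (17, 0.000441), hepatocytes (17, 0.000441) and pancreatic acinar cells (16, 0.0077), with 0 members of each adjusted over the list alone. Birc5 stood at 0.49, Tfrc at 0.44, Apoa2 at 1.94 and Ctrb1 at 1.67. These lists had an adjusted p = 0.624 with an estimated correlation, and pancreatic acinar cells an adjusted p = 0.697 with an estimated correlation. The hepatocyte median was 0.74 in OPP replicate 1 and between -0.11 and -0.03 in the other arrays of 1 week. The acinar median was -6.64 in water replicate 2 and -2.76 in OPP replicate 1. Without water replicate 2 the acinar median difference was -1.49 in place of 0.81, and without water replicate 3 that of the cell cycle list was -0.14 in place of 0.12 and that of erythroid cells -0.08 in place of 0.23. The erythroid median was -0.83 in water replicate 3 and between -0.10 and 0.06 in the other arrays of 1 week.

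In spleen at 4 weeks, Hsph1, Hspd1, Chordc1 and Bag3 rose with OPP and Dbp fell again. Hsph1, a heat shock protein, rose by 1.22 (SE 0.20, adjusted p 0.0114), Hspd1, the mitochondrial chaperonin, by 0.91 (SE 0.16), Chordc1, a partner of HSP90, by 0.77 (SE 0.15) and Bag3, a partner of HSP70, by 0.75 (SE 0.11). Tmem33 rose by 0.70, P4ha1, which hydroxylates collagen, by 0.64, and Mob4 by 0.47, though other probes of Mob4 gave -0.19 and 0.04. Dbp fell, with a difference of -1.45 (SE 0.20, adjusted p 0.00977), Tmsb10, an actin-binding peptide, with -1.04 (SE 0.16), Serp1 with -0.93 (SE 0.17) and H2-T22, a class I-like MHC gene, with -0.91 (SE 0.15). Also lower and called were Cacna2d3, a calcium channel subunit, with -0.87 (SE 0.13), Cat, the catalase that breaks down hydrogen peroxide, with -0.83 (SE 0.15), Nr1d2, a repressor of the clock, with -0.82 (SE 0.13) and Ctso, a cysteine protease, with -0.80 (SE 0.14). Second probes of H2-T22 and Nr1d2 gave 0.00 and 0.14. In all 80 probes were called, 8 higher and 72 lower, with 7 and 61 named genes. The number of calls changed with each array left out. It was 0 without water replicate 1, water replicate 2 or OPP replicate 3, 3 without water replicate 3, 15 without OPP replicate 2 and 271 without OPP replicate 1. With all arrays kept, the number was 5 with the replicate number as a block, 800 in a fit to these 6 arrays alone, 1375 with array weights, 133 with a robust prior and 139 after quantile normalisation.

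Of the lists in spleen at 4 weeks, heat shock had the smallest camera adjusted p, 4.52e-13: 3 of its 15 members rose, 12 did not pass, and 7 were higher adjusted over the list alone. It had an adjusted p = 0.191 with an estimated correlation. Dnajb1 stood at 0.70 without passing. Other lists that rose were neutrophils and granules (17 measured, camera adjusted p 0.000102, S100a8 0.51, Ngp 0.70), cell cycle (27, 0.00468, Tyms 0.50), erythroid cells (17, 0.00919, Rhag 0.60) and oxidative phosphorylation (54, 0.0147, Ndufa5 0.47 but Cox7b -0.40). No member of these 4 passed, either over all probes or adjusted over the list alone. With an estimated correlation the neutrophil list had an adjusted p = 0.716, erythroid cells an adjusted p = 0.823, and both others an adjusted p = 0.859 with an estimated correlation. The neutrophil median was -0.13 and -0.07 in OPP replicates 1 and 2, but -0.67 in OPP replicate 3, within the range of the water arrays (-0.73 to -0.38).

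Another 8 lists fell in camera in spleen at 4 weeks, T cells and interferon response with an adjusted p = 0.793 with an estimated correlation and the other 6 with an adjusted p = 0.586 with an estimated correlation. In MHC class II, whose proteins present antigen to helper T cells, H2-Aa fell by 0.72 (SE 0.13, adjusted p 0.0222), 9 of 10 members did not pass on the probes used for lists, and 4 were lower adjusted over the list alone (camera adjusted p 0.000102, adjusted p = 0.586 with an estimated correlation). In the circadian clock list Dbp and Nr1d2 fell, 15 of 17 did not pass, and 4 were lower adjusted over the list alone (0.0144, adjusted p = 0.586 with an estimated correlation). Immediate early genes had 2 falls, Klf4 (-0.51) and Btg2 (-0.60), 15 that did not pass and 3 lower adjusted over the list alone (0.00934, adjusted p = 0.586 with an estimated correlation). No member was called over all probes in B cells (13 measured, camera adjusted p 0.000102, Cd37 -0.44), NK and cytotoxic cells (16, 0.000183, Gzma -0.67), plasma cells and immunoglobulin (11, 0.00468, Jchain -0.94), T cells (14, 0.0126, Cd28 -0.31) and interferon response (26, 0.0262, Tap1 -0.47), which had 2, 4, 3, 0 and 2 lower adjusted over the list alone. B cells, NK and cytotoxic cells and plasma cells had an adjusted p = 0.586 with an estimated correlation, and T cells and interferon response an adjusted p = 0.793 with an estimated correlation.

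Averaged over the 3 times, the spleen comparison has the most arrays, 9 against 9, and tests the mean of the 3 OPP differences, which can differ between times. Tmsb10 fell, with a difference of -0.57 (SE 0.09, adjusted p 0.0157), Serp1 with -0.54 (SE 0.10), Tspan4, a membrane tetraspanin, with -0.50 (SE 0.07) and Lyz2, the lysozyme of myeloid cells, with -0.48 (SE 0.10). Falls were also called for H2-Aa with -0.48 (SE 0.07), H2-T22 with -0.48 (SE 0.09), Gatm, the first enzyme of creatine synthesis, with -0.47 (SE 0.11) and H2-Ab1 with -0.46 (SE 0.08). Among called genes with the same sign at all 3 times, the largest rises were Scgb2b2 by 0.25, Olfr69 by 0.24, Wars, which charges tRNA with tryptophan, by 0.22, Mob4 by 0.22 and R3hdm1 by 0.21. Other probes of Lyz2, H2-T22, H2-Ab1, Wars and R3hdm1 gave 0.16, 0.04, 0.12, -0.12 and -0.06, and those of Mob4 gave -0.15 and 0.02. In all 406 probes were called, 13 higher and 393 lower. After centring each array on its median, 13 were higher and 142 lower. With the replicate number as a block 93 were called, with array weights 953 and after quantile normalisation 205.

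The number of calls on the spleen average also changed, in both directions, when single arrays were left out. Without 1 of the 18-hour arrays the count was 41, 32 and 676 for water replicates 1, 2 and 3, and 761, 27 and 153 for OPP replicates 1, 2 and 3. Among the 1-week arrays it was 35 and 1118 without water replicates 1 and 3, and 35 and 42 without OPP replicates 1 and 3. At 4 weeks it was 16, 227 and 164 without water replicates 1, 2 and 3, and 28 and 20 without OPP replicates 2 and 3. In the circadian clock list 4 of 17 members fell: Dbp fell by 1.00 (SE 0.12), with Nr1d2 at -0.49, Nr1d1 at -0.30 and Tef at -0.39. The other 13 did not pass, and 6 were lower adjusted over the list alone (camera adjusted p 0.0146, adjusted p = 0.563 with an estimated correlation). MHC class II had 2 falls of 10 on the probes used for lists, H2-Aa and Cd74 (H2-Ab1 stood there with its other probe, 0.12), and 4 lower adjusted over the list alone (0.00432, adjusted p = 0.563 with an estimated correlation). Immediate early genes had 2 falls of 17, Klf4 and Junb, and 7 lower adjusted over the list alone (0.0015), amino acid catabolism 2 of 19, Ass1 and Oat, and 7 (0.0224), NK and cytotoxic cells 1 of 16, Il2rb, and 3 (0.0206), and ribosomal proteins 1 of 66, Rpl22, and 13 (8.8e-05). These 4 lists had an adjusted p = 0.563 with an estimated correlation. Heat shock rose (0.00592, adjusted p = 0.563 with an estimated correlation), with Hspd1 by 0.39 and Hsph1 by 0.47, 13 of 15 not passing, and 2 higher and 1 lower adjusted over the list alone. No member passed in B cells, T cells, acute phase, extracellular matrix, interferon response and plasma cells, which fell (camera adjusted p 0.0224, 0.00304, 0.007, 0.0224, 0.041 and 0.0384) with 3, 7, 0, 3, 5 and 2 lower adjusted over the list alone, and had an adjusted p = 0.563 with an estimated correlation. Nor did any in cell cycle and erythroid cells, which rose (0.0224 and 0.0146) with 0 adjusted over the list alone. Cell cycle had an adjusted p = 0.658 with an estimated correlation and erythroid cells an adjusted p = 0.572 with an estimated correlation. Without water replicate 3 of 1 week the cell cycle median was -0.07 in place of 0.04, and the erythroid call ended, with a median of 0.00 in place of 0.10.

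**Figure D2:**
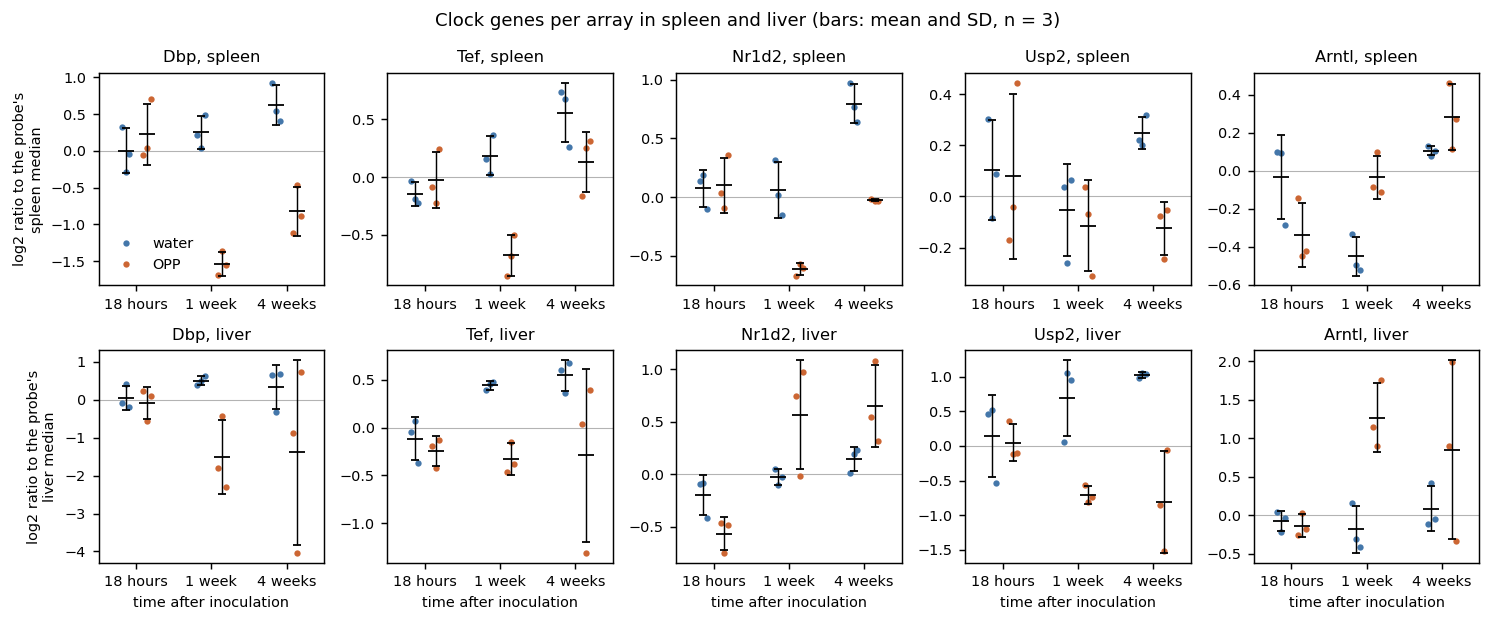
Log2 ratio of 5 clock genes to the probe's tissue median (vertical axes) on each array by time after inoculation (horizontal axes), water in blue and OPP in orange, with bars for the mean and SD of 3 arrays. The difference of Dbp in spleen is -1.78 at 1 week and -1.45 at 4 weeks, and that of Usp2 in liver -1.39 and -1.84.

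In liver at 18 hours, the genes with the smallest p were all lower with OPP: Bhmt, which remethylates homocysteine, with -0.58 (SE 0.10), Cmah, which hydroxylates sialic acid, with -0.45 (SE 0.09), Pja2 with -0.49 (SE 0.10), Cald1, an actin-binding protein, with -0.51 (SE 0.10) and Akap9 with -0.72 (SE 0.14; another probe 0.05). None passed, each having an adjusted p of 0.291. Alb and Cd79b had differences of -0.07 and -0.09; another Cd79b probe gave 0.01. Limma called 0 probes, with 1824 at an unadjusted p under 0.05, against 3 in a fit to these 6 arrays alone and 7 with array weights. Of the lists, 3 fell: genes higher in male liver (15 measured, camera adjusted p 3.45e-05, 8 lower adjusted over the list alone, Hsd3b5 -1.05), amino acid catabolism (19, 5.58e-05, 1 lower adjusted over the list alone, Aass -0.37) and bile acid synthesis and transport (16, 0.0218, 0 adjusted over the list alone, Cyp7b1 -1.27). Adipocyte genes rose (10, 0.0218, 0 adjusted over the list alone, Ucp1 2.52). No member passed over all probes. Bile acid genes had an adjusted p = 0.796 with an estimated correlation and the other 3 lists an adjusted p = 0.711 with an estimated correlation.

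In liver at 1 week, Tubb4b, Ddc and Mvd rose with OPP and Rgs16, Mt2 and Mt1 fell. Tubb4b, a tubulin, rose by 1.87 (SE 0.20, adjusted p 0.000237), Ddc, which makes dopamine and serotonin, by 1.85 (SE 0.25), Insc by 1.73 (SE 0.27) and Sqle, which oxidises squalene, by 1.54 (SE 0.36). Ppp1r3c and Ppp1r3b, which target a phosphatase to glycogen, rose by 1.52 (SE 0.35) and 1.45 (SE 0.33), Hacl1, of peroxisomal fatty acid oxidation, by 1.30 (SE 0.22) and Mvd, of the mevalonate pathway, by 1.29 (SE 0.20). Rgs16, a regulator of G-protein signalling, fell, with a difference of -4.21 (SE 0.71), the metallothioneins Mt2 and Mt1 with -3.64 (SE 0.49, adjusted p 0.00196) and -3.08 (SE 0.65), and Pcsk4 with -1.95 (SE 0.39; another probe 0.10). Further falls were Gpcpd1 with -1.85 (SE 0.42), Usp2, a deubiquitinase under clock control, with -1.39 (SE 0.32), Slc8b1 with -1.19 (SE 0.19) and Fam13a with -1.19 (SE 0.21). In all 222 probes were called, 169 higher and 53 lower. The count was 30 without OPP replicate 3, 80 and 85 without water replicates 3 and 2, and 341 without OPP replicate 1. It was 64 in a fit to these 6 arrays alone (28 higher and 36 lower), 120 with the replicate number as a block (84 and 36) and 397 after quantile normalisation (246 and 151).

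Cholesterol synthesis had the smallest camera adjusted p of the lists in liver at 1 week, 6.13e-17: 7 of 17 members rose, 10 did not pass, 15 were higher adjusted over the list alone, and the median was 0.99. It had an adjusted p = 0.211 with an estimated correlation. Beside Mvd, Pmvk rose by 0.99 (SE 0.18), Nsdhl by 1.10 (SE 0.21) and Idi1 by 1.07 (SE 0.21). Heat shock (camera adjusted p 1.69e-09) had 4 rises of 15, Stip1 by 0.80, Bag3 by 1.28, Hspb8 by 0.51 and Hsp90aa1 by 0.95, with 8 higher adjusted over the list alone. ER stress genes (5.92e-05) had 4 rises of 22, Atf4 by 0.92, Hspa5 by 1.05, Syvn1 by 0.95 and Manf by 0.79, with 6 higher adjusted over the list alone. Both lists had an adjusted p = 0.211 with an estimated correlation. No member passed in the lists of fatty acid synthesis (17, camera adjusted p 0.00452, Fasn 0.97), ribosomal proteins (66, 2.12e-05, Rpl35a 0.31) and male-biased genes (15, 0.0358, Elovl3 1.46), which rose with 1, 0 and 3 higher adjusted over the list alone. Nor did any in female-biased genes (16, 0.00274, Acot3 -1.54), adipocytes (10, 0.00804, Cidec -0.79) and extracellular matrix (19, 0.0372, Timp3 -0.64), which fell with 3, 2 and 1 lower adjusted over the list alone. The male-biased list had an adjusted p = 0.896 with an estimated correlation, female-biased 0.32, adipocytes 0.59, and the other 3 lists an adjusted p = 0.891 with an estimated correlation. Among the adipocyte genes, Adipoq stood at 3.01 in water replicate 3 and between -0.44 and 0.02 on the other arrays of 1 week.

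In liver at 4 weeks, Tubb4b rose again with OPP, by 1.41 (SE 0.20, adjusted p 0.0139), as did Pnkd by 1.12 (SE 0.20), Slc1a4, a neutral amino acid transporter, by 1.06 (SE 0.19) and Atf5, a stress-response transcription factor, by 1.03 (SE 0.15). S100a10 rose by 0.91 (SE 0.13), Ncald, a neuronal calcium sensor, by 0.84 (SE 0.14), Sdr9c7 by 0.77 (SE 0.14; other probes -0.11 and 0.59) and Nt5e, which makes adenosine, by 0.68 (SE 0.11). Usp2 fell, with a difference of -1.84 (SE 0.32, adjusted p 0.0368), Nmrk1, of NAD synthesis, with -1.07 (SE 0.18) and Osbpl5 with -0.68 (SE 0.10; another probe 0.02). The 15 called probes, 10 higher and 5 lower, shared 6 higher probes with those of 1 week (Atf4, Caprin1, Nt5e, Pnkd, Slc1a4, Tubb4b; 0.0705 by chance) and 2 lower ones, 1 of Usp2 and 1 without a gene symbol (0.0111 by chance). The chance numbers take the calls of both comparisons as independent. Both use the same spread of each probe from 1 fit, so these numbers may be too low. The count was 0 without water replicate 2 or OPP replicate 2, 2 without water replicate 1, 33 without water replicate 3 and 81 without OPP replicate 3. It was 35 with the replicate number as a block, 112 with array weights, 46 with a robust prior, 51 after centring, 163 after quantile normalisation and 26 over the more variable probes.

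The ER stress, heat shock and cholesterol synthesis lists rose again in camera in liver at 4 weeks, with an adjusted p = 0.132, 0.132 and 0.464 with an estimated correlation. In the ER stress list Atf4 rose by 0.68, 21 of 22 did not pass, and 6 were higher adjusted over the list alone (camera adjusted p 9.03e-07). It had an adjusted p = 0.132 with an estimated correlation, as had heat shock (15 measured, camera adjusted p 2.77e-10, 10 higher adjusted over the list alone, Hsp90aa1 0.99). No member of this and the following lists passed over all probes. Cholesterol synthesis (17, 7.99e-11, Hmgcs1 1.08), male-biased (15, 0.00358, Elovl3 1.81), amino acid catabolism (19, 0.0305, Cbs 0.73) and bile acid genes (16, 0.0497, Abcb11 0.71) rose with 6, 1, 3 and 2 higher adjusted over the list alone. Cholesterol synthesis had an adjusted p = 0.464 with an estimated correlation, amino acid catabolism 0.712, and the other 2 lists 0.601. The median of amino acid catabolism was -0.01 in place of 0.06 without water replicate 1 and -0.02 without OPP replicate 3, each ending its call. The cholesterol synthesis median was 0.47 and 0.46 in OPP replicates 1 and 3, but -0.24 in OPP replicate 2, within the range of the water arrays (-0.37 to -0.08). Pancreatic acinar genes (16, 2.67e-09, 0 adjusted over the list alone, Zg16 1.73) had a median difference of 1.62 and an adjusted p = 0.498 with an estimated correlation. The median was 4.87 in OPP replicate 1, and without that array the difference was -0.01. Ribosomal proteins (66, 7.99e-11, Rps9 -0.44), oxidative phosphorylation (54, 0.000117, Atp5j -0.44), macrophages (17, 0.0115, Vcam1 -0.58), female-biased genes (16, 0.0152, Acot3 -1.57) and MHC class II (10, 0.0445, H2-DMa -0.34) fell with 0, 1, 0, 3 and 0 lower adjusted over the list alone. Ribosomal proteins had an adjusted p = 0.501 with an estimated correlation, female-biased genes 0.464, and the other 3 lists 0.601. The MHC class II median was 0.05 in place of -0.14 without water replicate 3.

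Averaged over times, the largest rises in liver among called genes with the same sign at all 3 times were Nsdhl by 0.74 (SE 0.11, adjusted p 0.00778), Cyp51 by 0.68 (SE 0.13) and Pmvk by 0.51 (SE 0.10). Tubb4b, with -0.27 at 18 hours, rose by 1.00 on the average and falls outside this rule. They were followed by Egln3, an oxygen-sensing hydroxylase, by 0.44, Nt5e by 0.43, Dnase2a by 0.33, Rcan1, an inhibitor of calcineurin, by 0.28 and Stx18 by 0.25. Gpcpd1 fell, with a difference of -1.42 (SE 0.24), Usp2 with -1.11 (SE 0.18), Cpsf4l with -0.76 and Slc8b1 with -0.67. Hsd17b6, a steroid dehydrogenase, fell with a difference of -0.58, as did Sbk1 with -0.58, Tmem131l with -0.56 and Rnf152 with -0.56. Other probes of Cpsf4l gave -0.06 and 0.07, and another of Rnf152 gave 0.04. In all 83 probes were called, 41 higher and 42 lower. Cholesterol synthesis rose (camera adjusted p 1.18e-18) with Mvd, Nsdhl, Cyp51 and Pmvk called of 17 and 14 higher adjusted over the list alone, and had an adjusted p = 0.141 with an estimated correlation. Heat shock (2.88e-10, Stip1 called of 15, 9 higher adjusted over the list alone) and ER stress (1.08e-06, Atf4 called of 22, 8 higher adjusted over the list alone) rose, both with an adjusted p = 0.123 with an estimated correlation. Female-biased genes fell (0.00949, 0 of 16 called, 5 lower adjusted over the list alone), with an adjusted p = 0.481 with an estimated correlation. Pancreatic acinar genes rose (0.000816, 0 of 16 called, 0 adjusted over the list alone), with an adjusted p = 0.908 with an estimated correlation and a median of -0.03 in place of 0.54 without OPP replicate 1 of 4 weeks. For the 18-hour arrays the count was 38, 30 and 189 without water replicates 1, 2 and 3, and 33, 34 and 35 without OPP replicates 1, 2 and 3. For 1 week it was 54 and 35 without water replicates 1 and 2 and 54 without OPP replicate 2. For 4 weeks it was 32 and 53 without water replicates 1 and 2, and 37, 54 and 363 without OPP replicates 1, 2 and 3. It was 578 with array weights (164 higher and 414 lower), 148 after centring (73 and 75) and 331 after quantile normalisation (162 and 169).

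**Figure D3:**
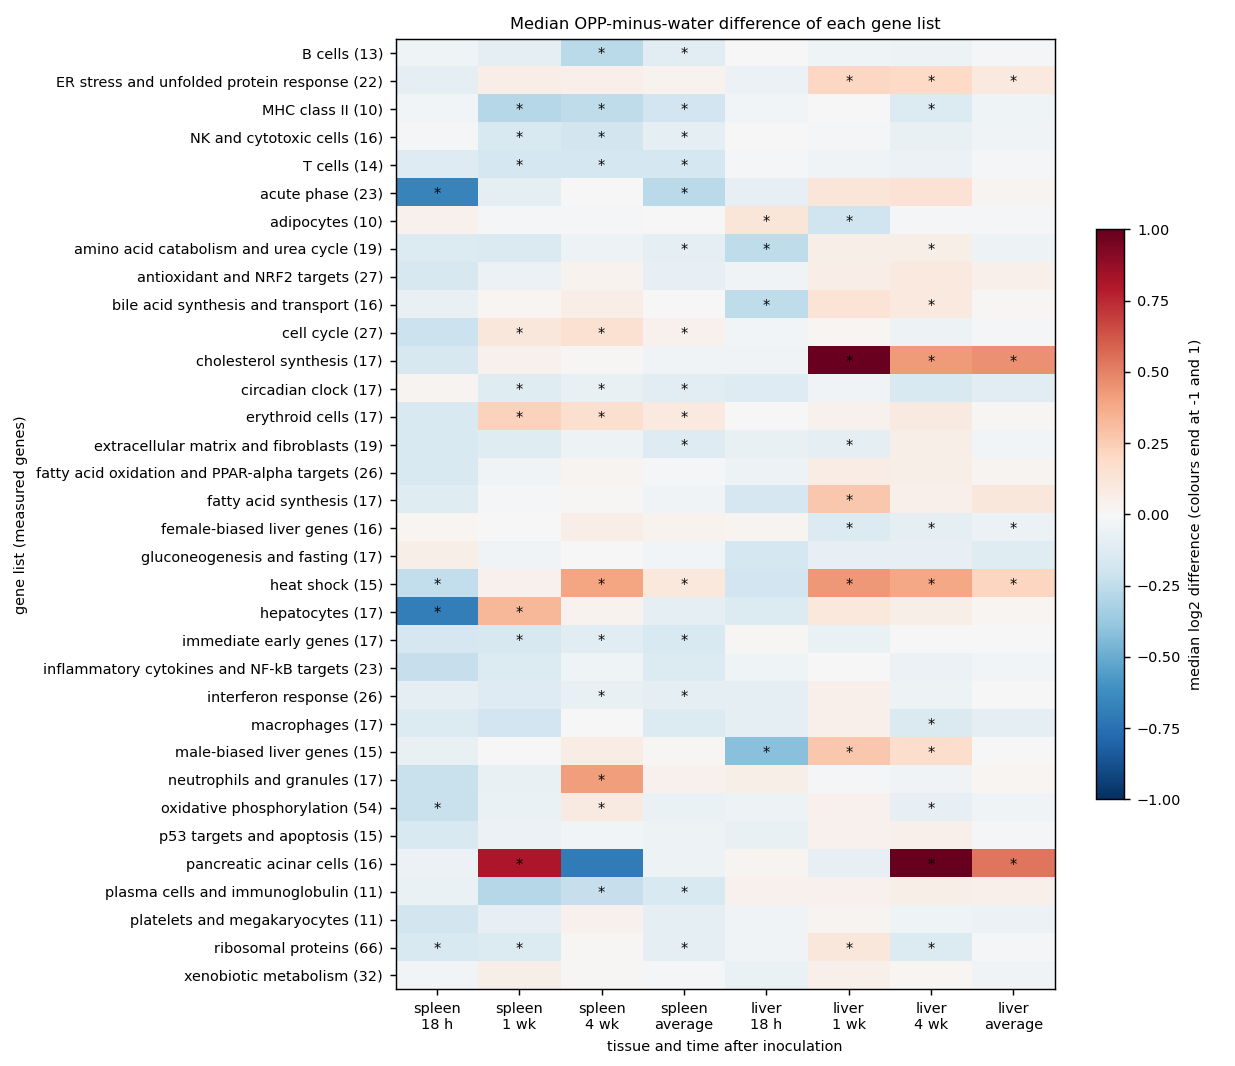
Median log2 difference between OPP and water (colour, ending at -1 and 1) of the measured members of 34 gene lists (vertical axis) in 8 comparisons (horizontal axis), with a star where camera called the list at its preset correlation. Cholesterol synthesis stands at 0.99 in liver at 1 week and heat shock at 0.39 in spleen at 4 weeks; no OPP list held with an estimated correlation.

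The water groups were compared between the sampled times, over which the mice also aged from 6 to 10 weeks. Time after inoculation, age and any sampling batch cannot be told apart, and no group was without inoculation. In liver the acute phase proteins, secreted in inflammation, fell steeply from 18 hours. At 1 week Saa3 fell, with a difference of -7.48 (SE 0.40, adjusted p 2.42e-09), Saa2 with -6.27 (SE 0.52), Lcn2, which binds bacterial siderophores, with -5.86 (SE 0.44), Crybb3 with -3.60 (SE 0.21) and Saa1 with -3.37 (SE 0.52). Hamp2, a paralogue of the iron hormone hepcidin, rose by 3.29 (SE 0.44), the glutathione transferases Gsta2 and Gsta1 by 3.29 (SE 0.44) and 2.69 (SE 0.37), Rgs16 by 2.91 (SE 0.71) and Car3, a carbonic anhydrase, by 2.35 (SE 0.27). At 4 weeks Saa2 fell with a difference of -7.28, as did Lcn2 with -7.18, Saa3 with -7.14, Mt2 with -5.70 and Saa1 with -4.53. Hamp2 rose by 3.68, Car3 by 2.87, Cyp2c54 and Cyp2b9, cytochromes P450, by 2.75 and 2.40, and Krt23, a keratin, by 2.33. At 1 week 1707 probes were called, 1070 higher and 637 lower. At 4 weeks there were 2208, 1418 higher and 790 lower. The first count was 860 without 18-hour replicate 3 and 1092 without 1-week replicate 1, and the second 1346 without 18-hour replicate 3 and 1434 without 4-week replicate 3.

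Of the 23 acute phase genes in liver 20 fell at 1 week and 21 at 4 weeks, the same numbers adjusted over the list alone (camera adjusted p 6.05e-41 and 3.2e-38). Orm2, an orosomucoid, fell, with differences of -2.44 and -2.80, and Steap4 with -2.30 and -2.24. The call held with an adjusted p = 0.0073 with an estimated correlation at 1 week and 0.00991 at 4 weeks. Inflammatory cytokines and NF-kB targets had 9 falls of 23 at 1 week, with Nfkbiz at -1.47 and Icam1 at -1.10, and 8 at 4 weeks, with 11 and 10 lower adjusted over the list alone (7.41e-10 and 2.46e-08). They had an adjusted p = 0.0073 and 0.00991 with an estimated correlation. Neutrophil and granule genes had 5 falls of 17 at both times, with S100a8 at -2.35 and -2.42, and 5 and 7 lower adjusted over the list alone (1.75e-06 and 2.63e-06), and an adjusted p = 0.036 and 0.0354 with an estimated correlation. Camera called 18 lists at each time, and the calls of the others did not hold with an estimated correlation. At 1 week xenobiotic metabolism had 12 rises and 2 falls of 32, 16 higher and 2 lower adjusted over the list alone (camera adjusted p 1.75e-06, adjusted p = 0.164 with an estimated correlation), with Cyp2c37 rising by 2.07 and Cyp3a13 at -1.42. Fatty acid oxidation had 10 rises of 26, 16 higher and 1 lower adjusted over the list alone (9.99e-06, adjusted p = 0.164 with an estimated correlation), and antioxidant genes 12 rises and 2 falls of 27, the same numbers adjusted over the list alone (4.73e-06, adjusted p = 0.234 with an estimated correlation). Ribosomal proteins had 19 falls of 66, with 1 higher and 29 lower adjusted over the list alone (4.11e-15, adjusted p = 0.272 with an estimated correlation). Cholesterol synthesis had 5 falls of 17, such as Sqle at -1.40, with 8 lower adjusted over the list alone (2.2e-05, adjusted p = 0.333 with an estimated correlation).

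**Figure D4:**
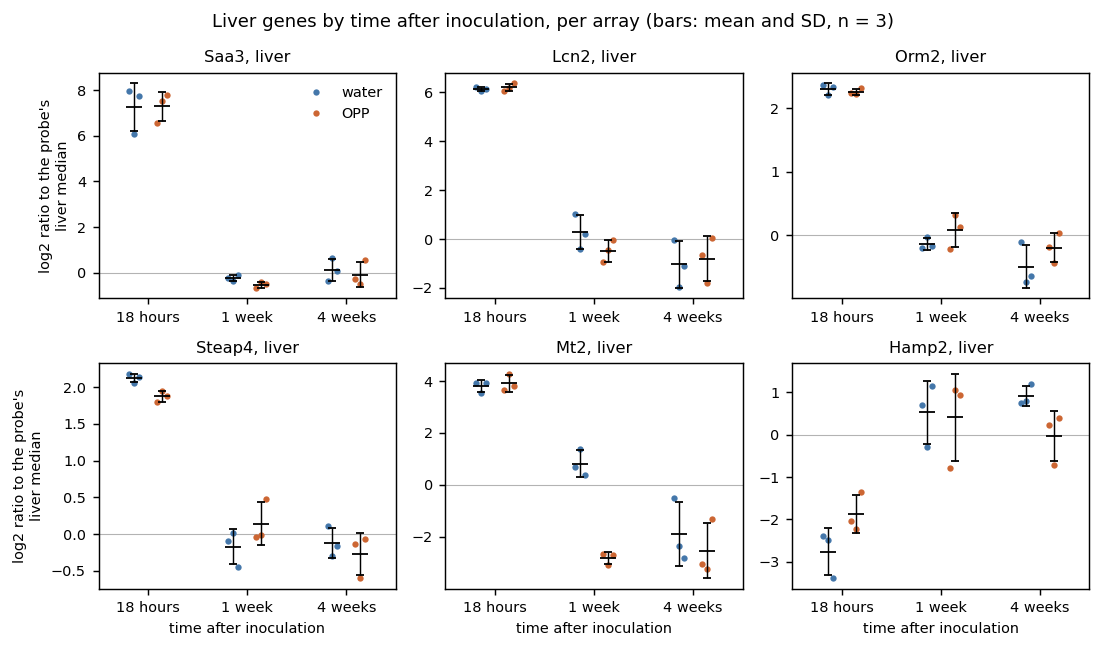
Log2 ratio of 6 liver genes to the probe's liver median (vertical axes) on each array by time after inoculation (horizontal axes), water in blue and OPP in orange, with bars for the mean and SD of 3 arrays. In water mice the difference of Saa3 is -7.48 and that of Lcn2 -5.86 between 18 hours and 1 week, and Hamp2 rose by 3.29.

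In spleen at 1 week against 18 hours in water mice, Reg2, Reg3a and Reg3b, secreted lectins of the Reg family, which the pancreas can make, fell, with differences of -4.89 (SE 0.82, adjusted p 0.0144), -3.89 (SE 0.68) and -3.57 (SE 0.81), Saa3 with -2.49 (SE 0.47) and Hpx with -2.03 (SE 0.45). The Ufl1 probe rose by 2.86, Tac2 by 0.92, Ccne1, the G1/S cyclin E1, by 0.83, Dnajb1 by 0.78 and Ubd, a ubiquitin-like modifier, by 0.73. In all 156 probes were called, 23 higher and 133 lower, and camera called 12 lists. Pancreatic acinar genes (16 measured, 0 called, 0 adjusted over the list alone, camera adjusted p 9.75e-06, adjusted p = 0.596 with an estimated correlation) had a median difference of -2.08, and 0.18 without 1-week replicate 2, whose acinar median was -6.64. Over the 6 fits that left out 1 array the differences lay between -5.45 and -3.94 for Reg2, -4.56 and -3.54 for Reg3a and -4.55 and -2.79 for Reg3b, and the calls ended in 1, 2 and 4 of them. Matrix genes (19 measured, 4 fell, 11 lower adjusted over the list alone, camera adjusted p 1.2e-09) included Col4a1, which fell by 1.00, and Col1a2 at -0.78, with an adjusted p = 0.0563 with an estimated correlation. Acute phase genes (23, 5 fell, 16 lower adjusted over the list alone, 7.09e-15) had an adjusted p = 0.132 with an estimated correlation, beside a median of -0.68 in hepatocyte genes (17, 1 fell, 11 lower adjusted over the list alone, 1.23e-08, adjusted p = 0.321 with an estimated correlation). Inflammatory genes (23, 6 fell, 8 lower adjusted over the list alone, 7.32e-06, adjusted p = 0.361 with an estimated correlation) included the falls of Il18 (-0.95) and Cd14 (-1.10), and macrophage genes (17, 3 fell, 7 lower adjusted over the list alone, 0.00298, adjusted p = 0.558 with an estimated correlation) those of Marco (-1.99) and Adgre1 (-0.95). The macrophage median was 0.02 in place of -0.24 without 1-week replicate 3, and 7 of the 17 members lay above 0. ER stress and amino acid catabolism also fell (0.00969 and 0.000715, with 0 and 1 called and 2 lower adjusted over the list alone in each; adjusted p = 0.462 and 0.287 with an estimated correlation). Cell cycle (1 called), erythroid cells, NK and cytotoxic cells and ribosomal proteins (0 called in each) rose in camera (1.23e-08, 0.000182, 0.000199 and 0.000361; adjusted p = 0.558, 0.596, 0.452 and 0.68 with an estimated correlation). The count was 2 without 18-hour replicate 2, and 103, 32 and 935 without 1-week replicates 1, 2 and 3. It was 31 in a fit to the 6 arrays alone (0 higher and 31 lower) and 578 after quantile normalisation (239 and 339). Array weights gave 101 higher and 98 lower, centring 28 and 200, and the replicate number as a block 23 and 163.

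At 4 weeks against 18 hours in spleen the median of all probes was higher by 0.14, so changes are given after centring each array on its median. Car1, the carbonic anhydrase of red cell precursors, rose by 1.49 (SE 0.23), Mrc1, the mannose receptor of macrophages, by 1.31 (SE 0.19), Sec14l2 by 1.18, Ubd by 1.16 and Tspan33 by 1.16. Reg2 fell, with a difference of -5.68 (SE 0.82), Reg3a with -4.87 (SE 0.68), Reg3b with -4.63 (SE 0.91), Saa3 with -3.03 (SE 0.47) and Cstdc6 with -2.48 (SE 0.46). As deposited 5838 probes were called, 5517 higher and 321 lower. Centred, 3484 were, 2504 higher and 980 lower, and after quantile normalisation 3291, 2031 higher and 1260 lower. Without 4-week replicate 1 the count as deposited was 2900. In centred values 13 of 17 neutrophil genes and 17 of 23 acute phase genes fell, while 9 of 10 MHC class II, 9 of 13 B cell, 8 of 16 NK and cytotoxic, 11 of 17 erythroid, 19 of 27 cell cycle and 42 of 66 ribosomal protein genes rose. Of 17 hepatocyte genes, which include sources of plasma proteins, 5 fell and 1 rose in centred values with a median of -0.63 (as deposited, camera adjusted p 3.09e-07, adjusted p = 0.206 with an estimated correlation, 2 higher and 7 lower adjusted over the list alone). Their median per array was 1.15 and 0.72 in 2 of the 3 water spleens of 18 hours. As deposited, 14, 18, 10, 12, 12, 16, 23 and 57 members of the first 8 lists passed in the same direction adjusted over the list alone (camera adjusted p 1.87e-19, 3.74e-22, 1.43e-05, 7.27e-05, 0.000288, 6.74e-05, 1.63e-06 and 5.32e-14). Acute phase genes had an adjusted p = 0.0603 with an estimated correlation, neutrophil genes 0.131, MHC class II, B cells and ribosomal proteins 0.206, NK and cytotoxic cells 0.262, and erythroid and cell cycle genes 0.48. Camera called 20 lists as deposited. Of these, 5 were placed lower while their median or mean lay above 0: bile acid genes (median 0.00, mean 0.04), female-biased genes (median 0.04, mean -0.04), inflammatory genes (median -0.03, mean 0.02), acinar genes (median 0.20, mean 0.08) and xenobiotic metabolism (median 0.01, mean -0.07).

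**Figure D5:**
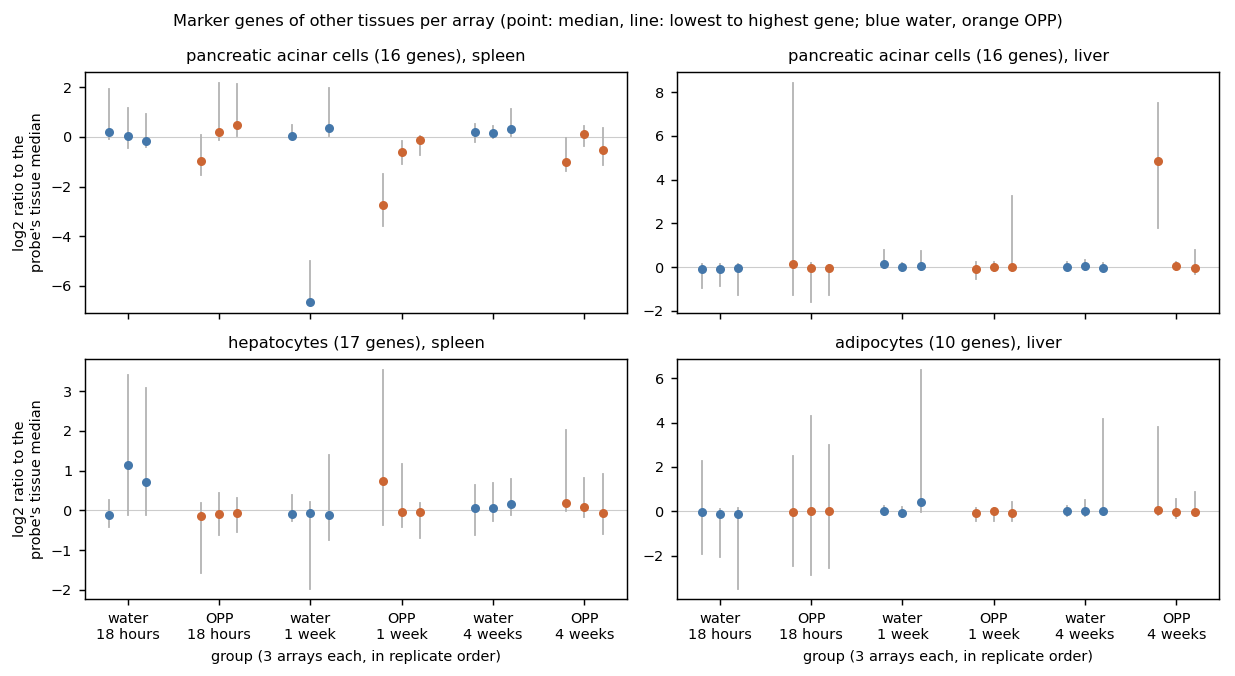
Log2 ratio to the probe's tissue median (vertical axes) of marker genes of other tissues on each array, grouped by drink and time (horizontal axes), with points for the median and lines from the lowest to the highest gene. The acinar median is 4.87 in liver in OPP replicate 1 of 4 weeks and -6.64 in spleen in water replicate 2 of 1 week, and the hepatocyte median in spleen is 1.15 in water replicate 2 of 18 hours.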

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

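The tests of the clock, acinar and Ufl1 patterns and the difference between tissues were chosen after the results were seen; the counts of other splits and the test of the OPP effect by time were planned.

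The OPP effect differed between liver and spleen for 65 probes at 1 week, higher in liver for 60, for 19 at 4 weeks (17) and for 46 on the average (40), tested as the difference itself in limma; at 18 hours 0 probes differed, with 1303 at an unadjusted p under 0.05. At 1 week the liver-minus-spleen difference was 1.97 for Tubb4b (adjusted p 5.69e-05), 1.99 for Ddc, 0.85 for Hspb8, 0.99 for Hspa5 and -4.09 for Rgs16. At 4 weeks it was 1.28 for S100a10 and 1.17 for Atf5. These differences came from 1 fit over all 36 arrays, with a mean per group and the spread of each probe pooled over both tissues. Spleen and liver may come from the same mice, which this fit did not take into account. It was not repeated with arrays left out. Because the ratios keep no level, a gene not expressed in 1 tissue cannot be told from a gene that did not respond there.

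In liver the OPP effect differed between times for 26 probes, most clearly Stip1, Tubb4b and Caprin1 (adjusted p 0.00894 each) and Bhmt, Cald1 and Alg2 (0.0173 each). Relative to the effect at 18 hours, those at 1 and 4 weeks were higher by 1.13 and 0.82 for Stip1, 2.14 and 1.69 for Tubb4b, 1.11 and 1.04 for Caprin1, 0.86 and 1.01 for Bhmt, 0.68 and 1.00 for Cald1, and 1.12 and 0.69 for Alg2. Of 100 splits 4 gave as many probes, a share that counts against chance by the rule set beforehand. Another split gave 255, well above the real 26, so this count alone does not exclude chance. A structure of the samples as its cause was not tested. The count was 6, 11 and 10 without 18-hour water replicates 1, 2 and 3, 6, 5 and 4 without 18-hour OPP replicates 1, 2 and 3, 17 without 1-week water replicate 2 or 3, 90 and 46 without 1-week OPP replicates 1 and 2, and 43 without 4-week water or OPP replicate 3. With the replicate number as a block it was 4, of which 2 were among the 26; Caprin1 kept its call and the other 5 named genes lost theirs. It was 102 with array weights, 52 with a robust prior, 39 after centring and 40 over the more variable probes. After quantile normalisation it was 28, with 18 of the 26, and Tubb4b lost its call (adjusted p 0.107).

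In spleen the OPP effect differed between times for 1 probe, Dbp (adjusted p 0.0400), whose difference was 0.23 at 18 hours, -1.78 at 1 week and -1.45 at 4 weeks. Of 100 splits 5 gave as many probes, the highest other 32, so chance is not excluded for this count. Next were Bag3 (0.142), Cacna2d3 (0.402), Dnaic1, Atp11a and Ufl1 (0.471 each), which did not pass. The count was 22 without 18-hour water replicate 1 and 2 without 4-week OPP replicate 1 or 2; it was 0 without 18-hour water replicate 3, 18-hour OPP replicates 2 or 3, 1-week water replicate 1, any 1-week OPP replicate, 4-week water replicates 1 or 2, or 4-week OPP replicate 3. Without 18-hour water replicate 2 Dbp lost its call and Ufl1 gained one. Of the other settings Dbp kept its call after centring only. Its adjusted p was 0.144 with the replicate number as a block, 0.0634 with array weights, 0.184 with a robust prior, 0.13 after quantile normalisation and 0.0549 over the more variable probes.

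Other splits of the arrays gave the following numbers of called probes. For the averages over times, 1 of 100 splits, the real one, gave as many as the real 406 in spleen (highest other 18). In liver 2 of 100 gave as many as the real 83. Both shares are under the 0.05 set beforehand as counting against chance. Another split in liver gave 875, so the liver count alone does not exclude chance. A structure of the samples as its cause was not tested. For the comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. In spleen the real and highest other counts were 0 and 5 at 18 hours, where all 10 splits gave as many, 2 and 0 at 1 week, and 80 and 0 at 4 weeks; in liver they were 0 and 1 (10 splits), 222 and 3, and 15 and 0. For the water groups they were 156 and 134 in spleen at 1 week, 5838 and 0 at 4 weeks, 1707 and 0 in liver at 1 week, and 2208 and 0 at 4 weeks; in these and the other OPP comparisons 1 split, the real one, gave as many.

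Dbp was lower with OPP in spleen at 1 and 4 weeks. In liver its differences of -2.01 and -1.72 did not pass (adjusted p 0.295 and 0.593). Other genes that peak with it went both ways: in liver Nr1d2 had 0.59 and 0.50, Nr1d1 -0.62 and 0.26, and Tef -0.77 and -0.84, none of which passed, while Usp2 was lower and called at both times. Leaving out 1 array kept Dbp called in spleen at 1 week (largest adjusted p 0.0165), which argues against 1 array deciding it, and quantile normalisation left an adjusted p of 0.00621, which argues against differences of scale. At 4 weeks leaving out 1 array took the adjusted p as high as 0.146, ending the call as an explanation by 1 array predicts. The difference stayed between -1.63 and -1.30 (-1.45, SE 0.20, with all arrays). Why the call ended was not tested. The mean of 5 genes that peak with Arntl was compared with that of 7 genes that peak with Dbp. The Arntl set lay higher in 4 of 4 combinations of tissue and time at 1 and 4 weeks. The gaps were 0.65 and 0.60 in spleen and 1.31 and 0.95 in liver, against -0.25 and 0.06 at 18 hours. The Dbp set holds Dbp, Nr1d2 and Usp2, already known to be called lower in spleen or liver, so the choice fixed part of the gap. Spleen and liver may also come from the same mice, so the 4 combinations may not be independent. A different hour of killing or feeding between the groups may give this gap, and cannot be told apart from OPP acting on the clock, because the labels give no hour. An unknown hour likewise limits the other differences between OPP and water, including those of the liver lists at 1 and 4 weeks. Whether it shaped them was not tested.

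Pancreatic acinar genes stood apart in single arrays. In liver OPP replicate 1 of 4 weeks, 15 of the 16 acinar genes lay over 1 log2 unit above every other liver array, so pancreas carried into that sample is a candidate explanation. An effect of OPP on these genes in liver would place all 3 OPP arrays above the water arrays; 2 were, and their median beside the 4.87 of replicate 1 was 0.07 in replicate 2. No biological explanation for the low acinar genes of spleen water replicate 2 of 1 week was tested. The ratios are to the median of the spleen arrays, so they do not show whether this array or the others were unusual.

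The Ufl1 probe had a high state (at least 3.25) in 4 spleen and 5 liver arrays and a low state (at most 0.46) in the others, while the gene's other probe lay between -0.38 and 0.29. In spleen 4 of 9 water and 0 of 9 OPP arrays were high, and in liver, which did not lead to the choice of this gene, 3 of 9 and 2 of 9. With the drinks exchanged within each time in liver, the 1-sided exact p of as few high OPP arrays was far above 0.05, so whether OPP lowers this probe stays open. High arrays numbered 3 at 18 hours, 6 at 1 week and 0 at 4 weeks, of 12 each. Of 18 pairs of spleen and liver arrays of the same group and number, 3 were high in both. With the numbers exchanged within each group the 1-sided exact p of as many was 0.333, and both states occurred in both tissues in 1 group, so a state of the animal shared by its tissues can be neither supported nor excluded. The labels do not state whether equal numbers are the same animal.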

How the results depend on the processing

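Centring, quantile normalisation, the robust prior, the more variable probes and the mean of a gene's probes were chosen after the data were seen; the other alternatives were planned. Not run, because they need the signals or detection p-values that match no sample: fits on background-corrected signals in any scaling, over 1 or both tissues, quantile normalisation of raw signals, detection filters, the BeadChip as a block and a variance trend. The cause of a move was not tested. Signal over background is not kept in the ratios, so no limit by level can be given.

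A fit to only the compared arrays called 800 probes in spleen at 4 weeks, 31 in spleen water at 1 week, 3 in liver at 18 hours and 64 in liver at 1 week. The replicate block gave 5 in spleen at 4 weeks, 93 on the spleen average, 0 in spleen by time, 120 in liver at 1 week, 35 at 4 weeks and 4 by time. Water and OPP arrays of the same number, tissue and time were correlated after subtracting each probe's group mean. These 18 pairs correlated between -0.291 and 0.213, 1 above 0.1. This gave no sign that the numbers pair water with OPP arrays, but cannot exclude it. It does not bear on whether spleen and liver arrays of the same number share a mouse. Array weights gave 1375 and 953 in spleen at 4 weeks and on average, 0 by time, and 7, 112, 578 and 102 in liver at 18 hours, 4 weeks, on average and by time. The robust prior gave 133 and 0 in spleen at 4 weeks and by time, 46 and 52 in liver at 4 weeks and by time. Centring gave 155 on the spleen average, 3484 in spleen water at 4 weeks, and 51 and 148 in liver at 4 weeks and on average. Quantile normalisation gave 139, 205, 578 and 3291 in spleen at 4 weeks, on average and in water at 1 and 4 weeks, and 397, 163 and 331 in liver at 1 week, 4 weeks and on average. The more variable probes gave 0 in spleen by time and 26 and 40 in liver at 4 weeks and by time. Of the 73 camera list calls over the OPP comparisons 0 held with an estimated correlation, 11 were also called by fry, and 33 were kept in every fit without 1 array. Platelets and megakaryocytes were called by fry alone, in liver at 18 hours and on average.

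Leaving out 1 array gave 0 to 35 probes in spleen at 18 hours, 1 to 3 at 1 week, 0 to 271 at 4 weeks, 16 to 1118 on average, 0 to 22 by time, and 2 to 935 and 2900 to 5142 in water at 1 and 4 weeks; in liver 0 to 0, 30 to 341, 0 to 81, 30 to 363, 4 to 90, 860 to 1404 and 1346 to 1806; and 68 to 81 lists. A group left with 2 arrays is assumed to vary like the other groups. Reversals: in spleen OPP at 1 week, Cela1 and the acinar list gave -0.059 and -0.51 after quantile normalisation, and in spleen water at 4 weeks fry took the other direction for bile acid, inflammatory and acinar genes (medians 0.0016, -0.028 and 0.20). Ranges over left-out arrays that crossed 0 were, in spleen OPP at 1 week, -0.00039 to 0.48 for Tpx2, -0.038 to 0.59 for Cdk1, -0.54 to 2.80 for Ctrb1, -0.81 to 2.59 for Cela2a, -0.93 to 2.43 for Try4, -0.91 to 2.09 for Cela1, -0.14 to 0.36 for the cell cycle list, -0.079 to 0.43 for erythroid cells and -1.49 to 2.00 for the acinar list. For the spleen average the cell cycle list had -0.068 to 0.11 and erythroid cells -0.0025 to 0.16. In spleen water at 1 week they were -3.34 to 0.0068 for Ctrl, -3.18 to 0.16 for Ctrb1, -3.28 to 0.083 for Try4, -3.28 to 0.18 for the acinar list and -0.43 to 0.019 for macrophages. At 4 weeks there they were -0.072 to 0.12 for bile acid, -0.045 to 0.050 for inflammatory and -0.026 to 0.033 for xenobiotic genes. In liver they were -0.26 to 0.13 for Alb at 18 hours, and at 4 weeks -0.37 to 0.013 for H2-Aa, -0.41 to 0.15 for H2-DMb1, -0.31 to 0.046 for MHC class II, -0.020 to 0.12 for amino acid catabolism and -0.015 to 2.42 for the acinar list, which on average had -0.028 to 0.80. In liver water they were -0.073 to 0.000037 for plasma cells at 1 week and -0.077 to 0.027 for matrix genes at 4 weeks.

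Of the named values, 653 stayed on their side of the threshold after centring (14 lost and 8 gained the call), 594 after quantile normalisation (39 lost, 41 gained), 608 with the replicate block (55 lost, 12 gained), 583 with array weights (13 lost, 79 gained) and 613 with the robust prior (45 lost, 17 gained).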

Other observations

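The overlaps between comparisons, the marker values per array and the single list members named here were chosen after the results were seen.

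Several lists chosen for a polyphenol drink and a tumour-bearing host had no camera call in any of the 8 OPP comparisons, though single members were called in some of them. Antioxidant and NRF2 targets (27 measured) had 1 called fall each in spleen at 4 weeks (Cat) and on the spleen average (Ephx1), and medians between -0.16 in spleen at 18 hours and 0.10 in liver at 4 weeks, the latter with a camera adjusted p of 0.103. Inflammatory cytokines and NF-kB targets (23) came nearest on the spleen average, with a median of -0.14, a camera adjusted p of 0.0526 and a called fall of Nfkbia, which also fell in liver at 1 week, and with 1 higher and 7 lower adjusted over the list alone. In gluconeogenesis and fasting genes (17) 2 rose and 1 fell in liver at 1 week, with a list median of -0.08 and a camera adjusted p of 0.332. Xenobiotic metabolism (32), fatty acid oxidation (26), p53 targets (15) and platelets (11) had camera adjusted p-values of 0.774, 0.332, 0.711 and 0.729 in liver at 1 week. Cd36 of fatty acid oxidation and Bcl2 of the p53 list fell on the spleen average. The platelet list was called by fry alone, in liver at 18 hours (adjusted p 0.0207) and on average (0.0356).

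Between tissues, the higher probes of liver at 1 week and of spleen at 4 weeks shared Bag3 and Chordc1, 2 probes against 0.0564 by chance. The chance numbers take the calls of both comparisons as independent. The lower probes of these comparisons shared 0 (0.159 by chance). On the averages, 5 lower probes were shared, with Osbpl5, Pnpla2, Slc8b1 and Tmem131l as their named genes, against 0.688 by chance, and 0 higher ones against 0.0222.

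Ucp1, the uncoupling protein of brown fat, was high in single livers of both drinks: 6.38 in water replicate 3 of 1 week, 4.14 in water replicate 3 of 4 weeks, 3.80 in OPP replicate 1 of 4 weeks, 2.25 in water replicate 1 of 18 hours, and 2.48, 4.28 and 3.01 in the OPP replicates of 18 hours. Adipoq stood at 3.01 in the first of these and at 1.30 and 1.15 in the next, at 1.04 in the water array of 18 hours, and between 0.45 and 1.38 in the OPP arrays of 18 hours.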
